A study of Mus musculus with 6 samples.

How the data were processed

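RNA of mouse bladder at embryonic day 18.5 had been measured on 6 arrays, 3 of Get1 −/− (null) and 3 of Get1 +/− (heterozygous) samples. Get1 is another name of Grhl3, a grainyhead-like transcription factor. Groups and replicate numbers came from the sample titles, in which the null arrays carry the numbers 1 to 3 and the heterozygous arrays the numbers 4 to 6, so no number pairs arrays across groups. The titles hold a further number, which is 1 for null 1 and 2 for the other 5 arrays, and its meaning is not given in the sources used here. The labels treat each array as a separate sample, and whether a sample held 1 bladder or a pool is not given.

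The deposited values are probe set intensity values on a linear scale, made by the authors with Affymetrix Expression Console 1.1 and PLIER 2.0 per the submitters' processing notes, which give neither the role nor the order of these tools. The background step and the normalization between arrays are not given in the sources used here. The values ran from 0.239 to 108984, and the upper quartiles of the 6 arrays lay between 336 and 372, so the arrays had already been brought to a similar scale. The labelling protocol in the labels describes a kit that makes sense-strand DNA for whole-transcript arrays, while the probe set names follow Affymetrix arrays that are usually hybridised with antisense RNA. Which protocol was used for these arrays could not be settled, and the labels give the same protocol for all 6. No genome build is given for the probes, so no positions are printed.

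Of 45101 probe sets, 64 were control probe sets. The platform annotation supplied with the values gave exactly 1 gene symbol for 34945 probe sets (77.5%) and several for 932, and 9160 others were unnamed here. Symbols were checked against the gene table of assembly GRCm38.p6 through gene identifiers, which altered 0 symbols. Probe sets with several symbols named no gene. A gene was represented by the probe set with the highest mean over all 6 arrays, which gave 18193 genes, of which 9010 had several probe sets.

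Values were taken as log2(value + 16), an offset in common use for PLIER signal, so fold changes are on that scale and understate the change of dim genes. The lowest possible level on this scale is 4. The 30% of genes with the lowest mean over all 6 arrays were left out (mean log2 under 5.80, a signal of 39.7), which left 12735 genes. Null and heterozygous arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are null minus heterozygous throughout, errors of group means are SDs over 3 arrays, and SE is the moderated standard error of the difference. For single genes an exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1. The number of arrays limits the precision.

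A total of 27 gene lists with 445 entries was fixed before the data were examined, for urothelium, epidermal processes and other cell types that a dissected bladder can hold. Of these entries 421 had a probe set and 344 were tested. The 25 lists with at least 3 tested members were tested with camera of limma (preset correlation between genes 0.01), adjusted over the 25 lists, and again with an estimated correlation and with fry. The fry test asks whether the genes of a list move on balance one way, and compares them with no other genes. Before the data were examined it was also fixed which genes are named: Grhl1, Grhl2, Grhl3 and the 5 uroplakins, the 15 largest called changes in each direction with separate groups, and up to 4 members per list with the smallest p. Unplaced gene models were left out of the naming, which concerned 2 higher and 0 lower genes. A further 8 lists of gut and neighbouring cell types were written after the gut genes had been seen to be higher. They left out the genes already called higher, and were written before their values as lists were looked at. The small intestinal list shares 4 genes with the intestine list, and the enteric list 2 with another fixed list. These members were thus already on fixed lists, and Fabp2 among them had a difference of 2.53 (adjusted p = 0.576 over all genes, limma).

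The fits were tested on simulated data in 3 against 3 arrays, with the heterozygous means and the spreads within groups of the real genes. The dim filter was applied again to the simulated values, which left 12735 genes. Simulated values were not held at the lowest possible level. Of genes changed by 1 on the log2 scale 6.45% were called, of those changed by 2 59.4%, and of those changed by 4 96.2%. These shares are of the 62, 64 and 53 changed genes that passed the filter, and changed genes that the filter removed are not counted in them. Of the calls 5.10% were unchanged genes. A list shifted by −1 was called lower, and 0 of the other lists were called. The simulated genes varied independently of one another, while the correlation estimated in the data was 0.37 for the intestine list. The simulation therefore does not test false list calls among correlated genes, nor the power for smaller shifts.

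Alternatives were the offsets 1 and 64, quantile normalization, centring each array on its median, no filter, a 50% filter, eBayes with trend and robust fitting, array weights, the mean of a gene's probe sets, a threshold of 0.10, a minimum of 1.5-fold, and leaving out each array. Leaving out null 1 and heterozygous 6 together was added after the data were seen. Intervals of list medians are bootstrap intervals over genes with 2000 resamples. They hold the spread over the genes of a list and not the spread between arrays, so they are no test of the groups. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3.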

Results

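Bladders of Get1 −/− and Get1 +/− mouse embryos at embryonic day 18.5 were profiled on 3 expression arrays per genotype. The question was which transcripts differ in animals whose bladder is defective, according to the series description. Get1 (Grhl3) encodes a grainyhead-like transcription factor of surface epithelia. Heterozygous animals served as the control group, and wild-type bladders were not analysed here. Median signals over all probe sets were 58.2, 68.3 and 70.4 on null arrays 1 to 3, and 64.5, 72.4 and 64.1 on heterozygous arrays 4 to 6. The 12735 genes tested had a median log2 difference of −0.03 between the groups.

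The Grhl3 probe set was read first, as a check of the labels. Its signal was 76.6, 21.5 and 119.7 on the null arrays and 143.3, 132.9 and 125.6 on the heterozygous arrays. On the log2 scale the level was 6.28 ± 0.95 in null and 7.23 ± 0.09 in heterozygous bladders (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The groups did not overlap, and the difference of −0.95 (SE 0.44) did not pass limma's test over all genes (adjusted p = 0.655). Without null 2, the array with the lowest signal, the difference was −0.42. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so it may check nothing. The related factors Grhl1 and Grhl2 had differences of −0.27 (adjusted p = 0.912) and 0.53 (adjusted p = 0.722), and that of Grhl2 was −0.01 when its probe sets were averaged.

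Reg3b and Reg3g, which encode antimicrobial lectins of the gut, rose by 7.64 and 5.34 on the log2 scale in null over heterozygous bladders, and Tff3 and Fcgbp, products of goblet cells, by 7.45 and 6.08. Their heterozygous means lay below the dim filter, so these sizes depended on the offset (4.34 to 5.92 for Reg3g with offsets of 64 and 1). Reg3b rose by 8.33 with an offset of 1. With an offset of 64 the brightest Reg3b probe set was another one, which rose by 7.37, so these values do not show the effect of the offset alone. Tff3 reached a log2 level of 13.23 ± 0.45 in null against 5.78 ± 0.47 in heterozygous bladders (SD, n = 3 each, adjusted p = 9.3e-05, limma), and Reg3b reached 13.00 ± 0.21 against 5.36 ± 0.39 (SD, n = 3 each, adjusted p = 3.6e-05, limma). Hnf4a, a transcription factor of gut and liver epithelium, rose from 7.14 ± 0.63 to 11.70 ± 0.26 (SD, n = 3 each, adjusted p = 8.7e-04, limma).

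In all, 57 genes were higher in null bladders at an adjusted p under 0.05, of which 50 differed by more than 4-fold and 23 by more than 16-fold. For 6 of the 57, among them Reg3b, Hnf4a and Lgals2, the probe set can also match other transcripts. The 15 with the largest change also held Lypd8, Reg1, Dmbt1, Mptx1, Spink4, Lgals2, Guca2a, Fabp1, Ces1c and Sval1, with log2 differences from 4.52 (Sval1) to 7.61 (Lypd8) and adjusted p from 9.3e-05 (Lypd8) to 0.0024 (Fabp1). Lypd8 encodes a surface protein of the colon epithelium, Guca2a the gut peptide guanylin, and Fabp1 a fatty acid binding protein of enterocytes and liver. On the heterozygous arrays most of these genes lay near the lowest level, so their folds depend on the offset. Fcgbp and Ces1c missed the threshold with an offset of 1 (adjusted p = 0.0591 and 0.0534), and Hnf4a missed it when its probe sets were averaged (log2 difference 1.19, adjusted p = 0.0885).

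**Figure D1:**
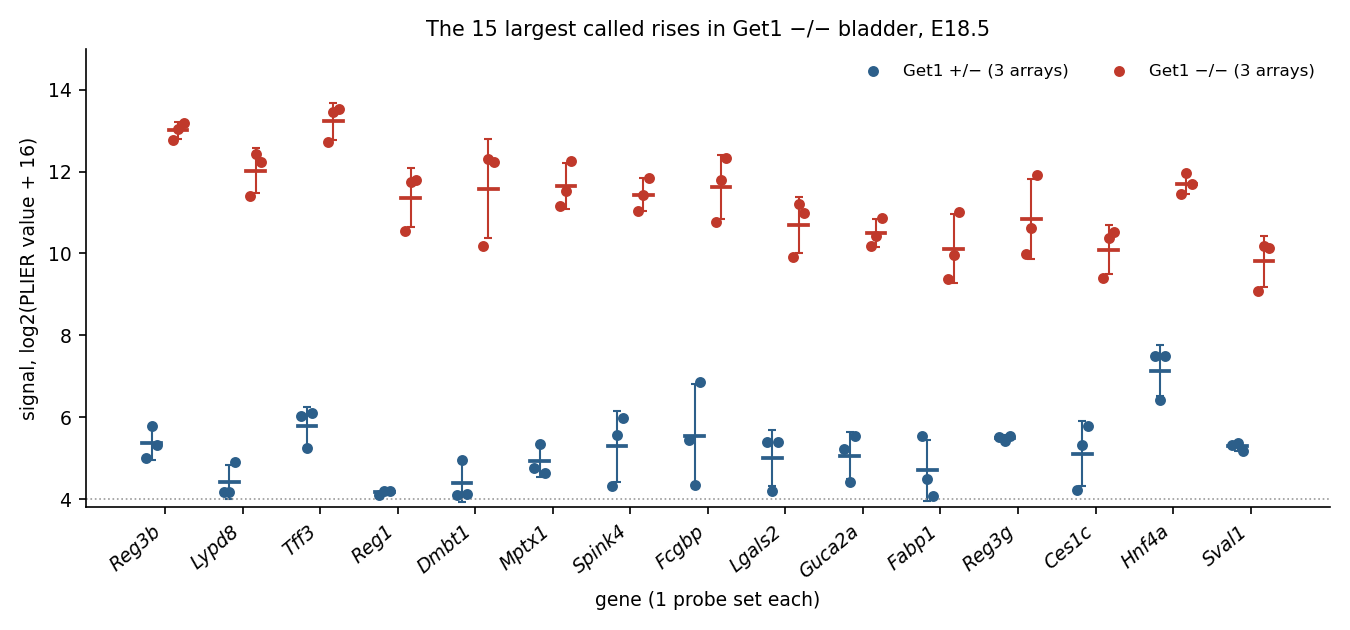
Signal of the 15 largest called rises, as log2(PLIER value + 16), in 3 heterozygous and 3 null arrays; points are arrays, bars are means and whiskers are SDs, and the dotted line at 4 is the lowest possible level. Every null array lay above every heterozygous array for each gene, for example at 12.72 to 13.53 against 5.24 to 6.09 for Tff3.

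Genes lower in null bladders were few and included products of the urothelial surface. Snx31, a sorting nexin that binds uroplakins in urothelium, fell from 10.19 ± 0.46 to 4.60 ± 0.53 on the log2 scale (SD, n = 3 each, adjusted p = 3.4e-04, limma). Its null level lay near the lowest possible one, so the size of the fall depended on the offset (log2 difference −7.25 with an offset of 1 and −4.05 with 64). Upk2, a uroplakin of the umbrella cell plaques, fell from 10.98 ± 0.28 to 7.95 ± 0.38, an 8.15-fold change (SD, n = 3 each, adjusted p = 0.0022, limma). Psca, a surface antigen, fell by 2.25 (adjusted p = 0.0445), and Sprr1a, a precursor of the cornified envelope, fell by 1.99 (adjusted p = 0.0093). The other genes that fell were Fam25c (−4.61), Fmo5 (−3.81), Cntnap2 (−2.36) and Tlcd4 (−1.62), which with those above made 8 genes at an adjusted p under 0.05. The probe set of Fmo5 can also match other transcripts.

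Over both directions, all 65 called genes had groups that did not overlap. At an adjusted p under 0.10 the counts were 65 higher and 12 lower, and at an unadjusted p under 0.05 they were 462 and 548. Groups did not overlap for 773 genes higher and 937 lower in null, 13.4% of genes against 10% by chance. Among the 5 arrays whose title has 2 as its first number, which leaves out null 1, 54 genes were higher and 7 lower. Of the calls, 34 higher and 5 lower genes (Cntnap2, Fam25c, Fmo5, Snx31 and Upk2) passed in each of the 6 fits that left out 1 array. Tlcd4 passed in 0 of these 6 fits (adjusted p from 0.0727 to 0.181), and Psca passed only without null 3, its adjusted p otherwise lying between 0.106 and 0.198. Sprr1a missed the threshold without null 2 (adjusted p = 0.0661) or heterozygous 5 (adjusted p = 0.0610), and the lower count was 5 when either of these arrays was left out. Without null 3, 38 genes were higher. Fam25c missed the threshold with an offset of 1 (adjusted p = 0.0558) and Cntnap2 with probe sets averaged (adjusted p = 0.0566). Psca also missed it with an offset of 1, without a filter and with array weights (adjusted p = 0.0986, 0.0799 and 0.0652). Tlcd4 passed in 1 of the 14 alternative fits that tested it.

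Of the 5 uroplakins, which form the plaques of the bladder surface, 1 fell over all genes tested and 2 fell when adjusted over the list alone. Beside Upk2, the list-alone call was Upk1a, at 8.23 ± 1.14 in null and 10.59 ± 0.22 in heterozygous bladders (SD, n = 3 each, log2 difference −2.36, adjusted p = 0.199 over all genes, limma). Upk1b, Upk3a and Upk3b had smaller differences of −0.55, −0.49 and −0.68 (adjusted p = 0.66, 0.687 and 0.732). The exact permutation p was 0.1 for Upk2 and Upk1a, 0.2 for Upk1b and Upk3a, and 0.3 for Upk3b. As a list the uroplakins were lower, with a median of −0.68 and a mean of −1.42 (camera adjusted p = 1.9e-05, adjusted p = 0.28 with an estimated correlation, fry adjusted p = 0.0295). Upk1a passed over all genes in 1 of the 6 fits that left out an array, the one without null 1 (−2.94, adjusted p = 0.0267), and in the others the difference was as small as −1.79 and the adjusted p as high as 0.492.

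**Figure D2:**
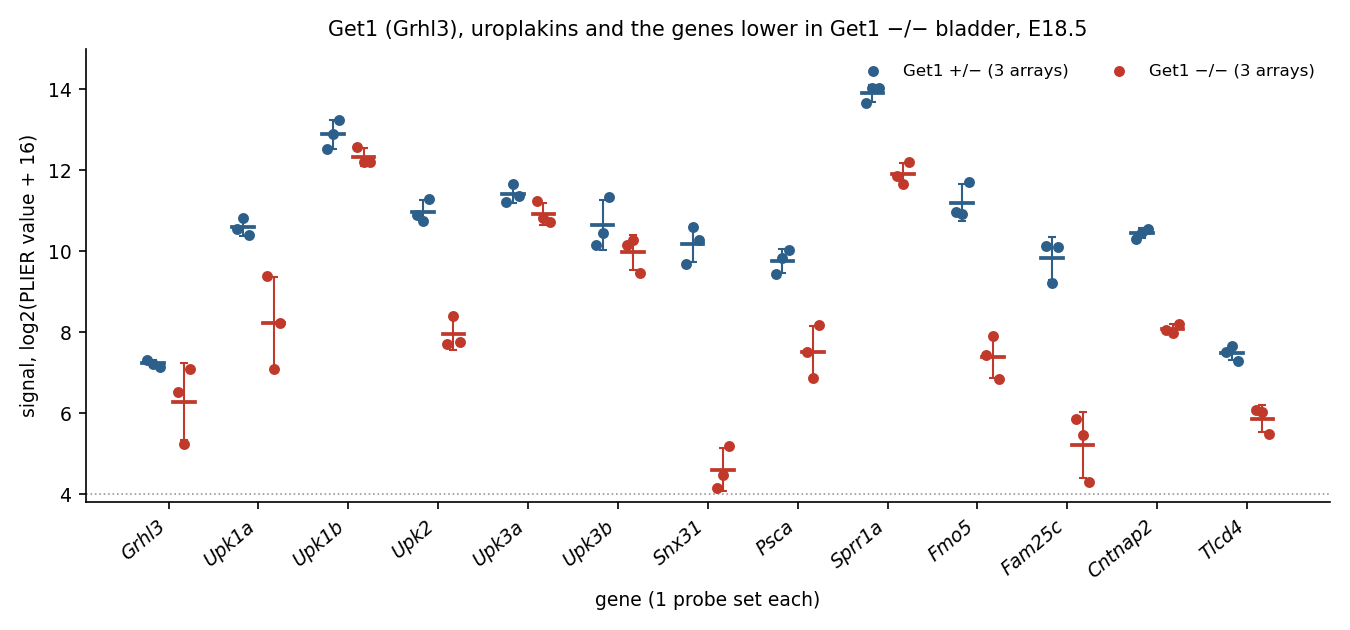
Signal of Grhl3, the 5 uroplakins and the other genes lower in null bladders, as log2(PLIER value + 16), in 3 heterozygous and 3 null arrays; points are arrays, bars are means and whiskers are SDs, and the dotted line at 4 is the lowest possible level. Snx31 lay at 10.19 in heterozygous and 4.60 in null bladders on average, while Upk1b lay at 12.88 and 12.33.

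The wider list of umbrella cell genes did not pass as a list. Of 14 tested members of the list for apical trafficking and keratin 20, 2 fell, Snx31 and Psca, and the same number fell when adjusted over the list alone. Rab27b and Mal had differences of −0.71 and 0.67, neither past the test (adjusted p = 0.526 and 0.59). The median was −0.06 and the mean −0.51 (camera adjusted p = 0.409). The median was above 0 with array weights (0.03), and without null 1, null 2 or heterozygous 6 (0.06, 0.08 and 0.03).

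The intestine list moved furthest of all lists. Of its 11 tested members 8 rose, and 9 rose when adjusted over the list alone. Its median was 4.06 (camera adjusted p = 3.5e-27, adjusted p = 0.144 with an estimated correlation, fry adjusted p = 0.0078). Beside Tff3, Guca2a and Fabp1, Vil1, which bundles actin in microvilli, rose by 3.72 and Cdh17, an intestinal cadherin, by 3.02. The mean of the list lay above the heterozygous mean by 3.02 on null 1, 4.19 on null 2 and 4.53 on null 3. Of the 13 members with a probe set, 4 had a heterozygous mean above the dim filter. A total of 49 genes outside the list also rose.

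The medians of 4 lists of epithelial layers and junctions were 0.31 (basal), 0.31 (luminal), 0.28 (tight junctions) and 0.32 (desmosomes), each with a camera adjusted p of 0.0219. With an estimated correlation the calls were lost, at adjusted p = 0.388 with an estimated correlation for desmosomes and adjusted p = 0.436 with an estimated correlation for the other 3. On the same arrays the intestine list was higher by 3.02 to 4.53. Of 14 basal urothelial markers 0 passed over all genes and 1 rose when adjusted over the list alone, the laminin chain gene Lama3 (1.23). Shh, an epithelial signal, and Krt15, a basal keratin, had differences of 1.00 and 0.73, and that of the nerve growth factor receptor Ngfr was −0.80 (adjusted p = 0.388, 0.543 and 0.433). Of 18 luminal keratins and regulators 0 passed by either count, with Krt19 at 1.15 and Foxa1 at 0.69 (adjusted p = 0.28 and 0.553). Of 17 tight junction genes 0 passed over all genes and 2 rose when adjusted over the list alone, Cldn7 (1.07) and Tjp3 (0.95). Of 16 genes of desmosomes and adherens junctions 0 passed by either count, with Cdh1 at 0.84 and Dsc2 at 0.98 (adjusted p = 0.308 and 0.353).

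Without null 3 the camera adjusted p of these 4 lists was 0.0647 (basal), 0.149 (luminal), 0.173 (tight junctions) and 0.0630 (desmosomes), and without heterozygous 4 it was 0.258, 0.195, 0.195 and 0.17. Without null 1 it was 0.0560 for the basal and the desmosome list, and without heterozygous 6 it was 0.0734 for the basal list. The lowest medians with 1 array left out were 0.13 (luminal) and 0.12 (tight junctions), both without null 3. For the basal list the lowest was 0.18, without heterozygous 4, and for desmosomes 0.19, without null 1.

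In the list for epithelial stress and wound response 0 of 13 genes passed over all genes and 3 rose when adjusted over the list alone: S100a9 (1.84), Krt6a (2.19) and S100a8 (1.61), whose adjusted p over all genes was 0.0613, 0.0826 and 0.125. Krt6a, a keratin of activated epithelium, passed over all genes without heterozygous 6 (adjusted p = 0.0251), and S100a9 and Krt6a also passed with an offset of 64 (adjusted p = 0.0210 and 0.0256). In all, S100a9 and Krt6a each passed in 6 of 16 alternative fits and S100a8 in 1 of 16. The list had a median of 0.40 (camera adjusted p = 0.0219, adjusted p = 0.395 with an estimated correlation). Its call was lost without heterozygous 4 (median 0.16, camera adjusted p = 0.180). It was also lost without null 1 and heterozygous 6 together (median 0.41, camera adjusted p = 0.0705). Without heterozygous 5 the median was 0.18 and the call held (camera adjusted p = 0.0155). The list of proteases and inhibitors of epithelial barriers had 0 of 8 members past the test by either count, with St14 at 1.01 and Tmprss4 at 1.35. Its median was 0.35 (camera adjusted p = 0.0219, adjusted p = 0.436 with an estimated correlation), and its call was lost without null 2, null 3 or heterozygous 4 (adjusted p = 0.0549, 0.0990 and 0.17).

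Epidermal programmes, for which Grhl3 is known in skin, did not pass as lists. Of 13 genes of epidermal cornification 1 fell, Sprr1a, also when adjusted over the list alone. Scel and Sbsn had differences of 0.89 and 0.60 (adjusted p = 0.523 and 0.515), and the median of the list was −0.37 (camera adjusted p = 0.414). With 1 array left out this median ranged from −0.42 to −0.016. Of 15 genes of barrier lipid metabolism 0 passed by either count, with the ceramide synthase Cers3 at −0.85 and the fatty acid hydroxylase Fa2h at 0.92 (adjusted p = 0.324 and 0.399), and the median was 0.10 (camera adjusted p = 0.473). Of 15 genes of the grainyhead-like family and planar polarity 0 passed by either count, with Celsr1 at −1.02 (adjusted p = 0.526) and a median of −0.17 (camera adjusted p = 0.737).

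Among genes of urothelial transport and sensing, the carbonic anhydrase Car2 rose by 2.94 (SE 0.34, adjusted p = 0.0085), on the same arrays as the gut genes. Which cells made Car2 was not measured. Car2 was the 1 call among 9 tested members. When adjusted over the list alone 2 rose, Car2 and the potassium channel Kcnn4 (1.16), and 1 fell, the urea transporter Slc14a1 (−1.11, adjusted p = 0.213 over all genes). The median of the list was −0.07, its mean 0.31, and camera gave an adjusted p of 0.414. Car2 missed the threshold without null 3 (adjusted p = 0.0521), and the median was above 0 without null 1, null 3, heterozygous 4 or heterozygous 6 (0.14, 0.06, 0.04 and 0.06). In the retinoid list 0 of 12 genes passed over all genes and 1 fell when adjusted over the list alone, Adh7, a retinol-oxidising dehydrogenase (−2.45, adjusted p = 0.0623 over all genes). The list had a median of −0.37 (camera adjusted p = 0.0543) and passed without null 1 or null 2 (adjusted p = 0.0443 and 0.0333). It also passed with an offset of 64, quantile normalization or centring (adjusted p = 0.0471, 0.0451 and 0.0376), and Adh7 passed without null 3 (adjusted p = 0.0180). Adh7 passed in 4 of the 15 alternative fits that tested it.

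**Figure D3:**
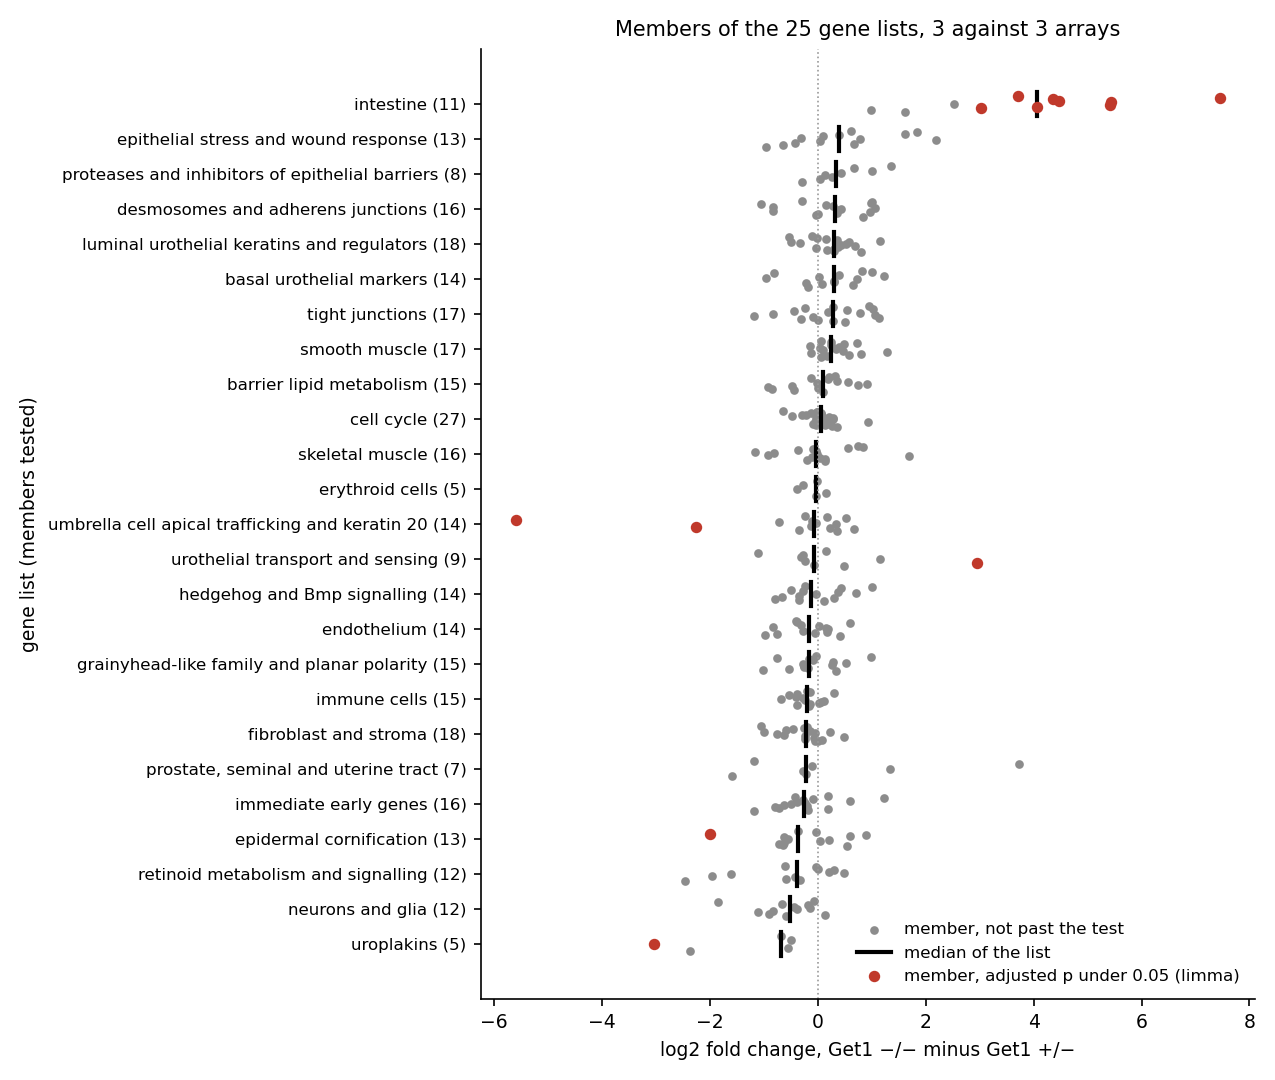
Log2 fold change (null minus heterozygous, 3 arrays each) of every tested member of 25 gene lists, with the number of members in brackets; grey points are members, red points are members with an adjusted p under 0.05, and black bars are list medians. The intestine list has a median of 4.06, and the medians of the other lists lie between −0.68 and 0.40.

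Lists of smooth muscle, nerve and stroma had medians between −0.51 and 0.24. Of 17 smooth muscle genes 0 passed by either count, with Des at 0.80, Cnn1 at 0.58 and Synpo2 at 0.73 (adjusted p = 0.281, 0.48 and 0.59), and the median of 0.24 was called higher (camera adjusted p = 0.0020, adjusted p = 0.436 with an estimated correlation). This call was lost without heterozygous 6 (median 0.07, adjusted p = 0.0597). Of 12 neuronal and glial genes 0 passed by either count, with tyrosine hydroxylase Th at −1.85, Phox2a at −1.11 and Gap43 at −0.90 (adjusted p = 0.515, 0.553 and 0.59), and the median of −0.51 was called lower (camera adjusted p = 0.0107, adjusted p = 0.436 with an estimated correlation). Without null 1 this median was −0.23 (camera adjusted p = 0.0443) and without null 3 it was −0.83, and the call was lost without null 1 and heterozygous 6 together (−0.30, camera adjusted p = 0.0585). The mean of the list relative to the heterozygous mean was −1.10 on null 1, −0.58 on null 2 and −0.07 on null 3, against −0.17 on heterozygous 4. Of 18 fibroblast and stromal genes 0 passed by either count, with Fbln2 at −1.0 and Dpt at −0.76 (adjusted p = 0.433 and 0.48), and the median of −0.21 was called lower (camera adjusted p = 0.0416, adjusted p = 0.634 with an estimated correlation). The stromal call held in 1 of the 6 fits that left out an array, the one without heterozygous 4 (adjusted p = 0.0081), and was otherwise between 0.0549 and 0.317.

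In the remaining lists 0 genes passed over all genes. Medians were 0.06 for cell cycle, −0.03 for skeletal muscle, −0.21 for immune cells, −0.17 for endothelium, −0.25 for immediate early genes, −0.04 for erythroid cells and −0.13 for hedgehog and Bmp signalling, with camera adjusted p from 0.364 to 0.975. In the list for prostate, seminal and uterine tract, 2 genes rose when adjusted over the list alone, Spink1 (3.74) and Hoxb13 (1.35), with adjusted p = 0.207 and 0.26 over all genes, while the median was −0.22 and the mean 0.24 (camera adjusted p = 0.737). Spink1 passed over all genes in 2 of the 15 alternative fits that tested it. Skeletal muscle passed without null 1 (median 0.45, adjusted p = 0.0299) or heterozygous 5 (median 0.07, adjusted p = 0.0336), and immediate early genes passed without heterozygous 4 (median −0.72, adjusted p = 0.0095). The skeletal muscle list had a mean of 0.03, opposite in sign to its median, and for hedgehog and Bmp signalling camera and fry gave opposite directions. Adipocyte and sex-linked lists had too few tested members for a list test. In all, 8 lists were called higher and 3 lower with the preset correlation, 0 with an estimated correlation and 2 with fry (intestine and uroplakins).

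Across all tested genes the groups did not overlap along the component with the most variance, which held 38.4% of it. The spread within each group was wider than the gap between the groups. Null arrays scored −44.2, −10.9 and −20.3 and heterozygous arrays 5.08, 14.1 and 56.2, so null 1 and heterozygous 6 stood at the ends. Pearson correlations over genes, which are not independent replicates, were 0.962 to 0.973 between null arrays, 0.941 to 0.969 between heterozygous arrays and 0.915 to 0.957 between groups. Heterozygous 6 differed from the others in its control probe sets. Its log2 signal at the 3′ end exceeded that at the 5′ end by 3.32 for Gapdh and 3.52 for Actb, against 0.889 to 1.72 and 1.74 to 2.35 on the other 5 arrays. Without heterozygous 6, 42 genes were higher and 7 lower.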

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

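The fit over unnamed probe sets was added once the data had been seen, while the count of splits was planned. Among 4782 tested probe sets without a gene name here, 1 was higher in null bladders and 0 were lower, in a limma fit over all 31526 tested probe sets. It lay at 9.80 in null and 6.69 in heterozygous bladders on the log2 scale (difference 3.11, adjusted p = 0.0424), a signal outside the comparisons of named genes. A further 2 probe sets that match several genes were also higher.

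The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of the 10, the real one, gave as many as 57 genes higher or 8 lower. The highest count among the other splits was 1 in either direction. Because 10 splits cannot give a share under 0.1, this is too few to decide on chance.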

How the results depend on the processing

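Leaving out null 1 and heterozygous 6 together was chosen after the result was seen, and the other alternatives were planned. Counts of 57 higher and 8 lower genes became 35 and 5 with an offset of 1, while the lower count was 5 with the 50% filter, in which fewer genes are tested, and 5 without null 1 and heterozygous 6. Leaving out 1 array gave 38 to 54 higher and 5 to 9 lower genes. The called genes that were tested kept their sign in each alternative fit, and the higher count was 66 with an offset of 64, 57 with quantile normalization, 65 with centring, 54 without a filter, 67 with trend and robust fitting, 77 with array weights and 61 with probe sets averaged. With these 7 settings between 8 and 12 genes were lower. Grhl3 kept its sign and stayed short of the threshold wherever it was tested (−1.35 to −0.42 when 1 array was left out), and it was too dim for the 50% filter. The 8 lists called higher became 4 with the 50% filter, 4 without both arrays, 0 with an estimated correlation, 1 with fry and 2 to 9 when 1 array was left out. The 3 called lower became 0 with an estimated correlation, 1 with fry and 2 to 4 when 1 array was left out. With an estimated correlation the adjusted p was 0.144 for the intestine list and 0.28 for the uroplakins, which were called in all 6 fits that left out 1 array. The 50% filter ended the calls of the basal (adjusted p = 0.0508), luminal (0.0567), tight junction (0.279), protease (0.0595) and stromal (0.0595) lists, and the stromal call was also lost without a filter (0.0573) and with array weights (0.135). Medians of lists that were not called changed sign as follows, and for these and the moved counts the cause was not tested. Skeletal muscle was 0.024 with an offset of 64, 0.020 with centring, 0.075 with array weights, 0.21 without both arrays and −0.40 to 0.45 with 1 array left out. Erythroid cells were 0.0089 with centring and −0.40 to 0.23 with 1 array left out. Barrier lipid metabolism was −0.011 without a filter and −0.11 without both arrays, and cornification was 0.044 with the 50% filter and 0.0079 without both arrays. Hedgehog and Bmp signalling was 0.045 with the 50% filter, and limma's fry gave it the opposite direction to camera (adjusted p = 0.823). With array weights, immediate early genes, immune cells, the umbrella list and transport were 0.10, 0.018, 0.027 and 0.0059, and without both arrays they were 0.27, 0.059, 0.12 and 0.15. With 1 array left out they ranged from −0.72 to 0.14, −0.37 to 0.14, −0.16 to 0.082 and −0.22 to 0.14, and cell cycle ranged from −0.043 to 0.11. Grhl2 was −0.014 with probe sets averaged, and Xist was −0.0047 to 0.34 with 1 array left out. No scaling moved the median of all genes by more than 0.1. Signal near the lowest level limits the folds of dim genes.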

Other observations

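The added gut lists, the tests of urothelial lists and the test of bacterial controls were chosen only after the gut genes, the uroplakins and heterozygous 6 had been seen, while the test of Gapdh and Actb was planned. In the list of the goblet and secretory lineage, 6 of 11 members had separate groups with null higher and the median was 0.99 (interval 0.48 to 1.44). The stomach list had a median of 0.61 (0.0036 to 1.504), with 4 of 11 members separate and higher and 1 separate and lower. The added lists held 0 called genes, which says nothing, because genes already called higher had been left out of them. Crypt and stem cell genes had a median of 0.03, enteroendocrine genes of −0.22, and genes of liver and pancreas of −0.29 (−1.13 to 0.03). Genes of enteric neurons and interstitial cells of Cajal had a median of −0.60 (−0.98 to −0.22), of which 10 of 11 also lay above the dim filter in heterozygous bladders and 2 are on another list. The most abundant tested genes of the small intestinal list were Apoa1 (8.78 ± 2.15 in null, 6.33 on null 1, against 7.16 ± 1.46) and Lct (8.71 ± 0.50 against 7.56 ± 0.39), and 8 of its 15 genes were above the dim filter in heterozygous bladders and 4 are also on the intestine list. The 1 tested colonocyte gene was Slc26a3 (6.24 ± 0.37 against 5.54 ± 0.38).

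Xist, transcribed from the inactive X chromosome, lay at 12.5 to 13.2 on all 6 arrays, while the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 4.08 and 7.16 and were left out as dim. These 3 genes were named after their values were seen.

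Gut epithelial genes were higher on all 3 null arrays, and gut tissue carried over at dissection and a change within the null bladder may each account for it. The small intestinal list had a median of 0.99 (interval 0.15 to 1.62). A median above 2 had been set beforehand as speaking for a small intestinal source and one below 1 against it. The median thus lay just below the bound against this source. The source is left open because the interval reached above 1, and because the list was written without the genes already called higher. Genes of this list differed between null arrays 1 to 3. Mttp lay at 6.45, 8.70 and 9.43 against a heterozygous mean of 7.80, and Apoc3 at 5.31, 7.29 and 8.28 against 5.76. Lct lay above its heterozygous mean of 7.56 on each, at 8.42, 8.42 and 9.29. The 3 enteric genes with a heterozygous mean log2 under 7 had a median of −0.22, and ran from −1.11 (Phox2a) to 0.08 (Kit). Their median lay below the bound of 0.5 set beforehand against whole gut wall. Gut wall is left open because 2 of them lay near the dim filter, at 5.47 and 5.81. The colonocyte list had a median of 0.72 (0.0089 to 0.81), below the bound of 1 set beforehand against a colonic source. That source is left open because the list was written without the genes already called higher, among them the colon gene Lypd8. This reason, which was also used for the small intestinal list, and that for the gut wall were set after the values were seen. The basal urothelial list had a median of 0.31 (−0.19 to 0.73), so its genes were not lower as a set. Replacement of a large part of the urothelium by gut-type epithelium needed a median below −0.5. That replacement stays open, because the bound was set after the gut genes had been seen. Gut-type epithelium may also make some of these genes, which was not measured. Carried-over gut epithelium and gut-type cells in the null bladder could not be told apart with these lists, because either brings the same transcripts. Carried-over gut wall would also bring enteric genes, but the dim enteric genes could not decide on it, for the reason given above. A direct effect of genotype was not tested.

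Upk2 and Snx31 were lower on the null arrays, with Upk1a lower on average but not called. Degraded RNA in the null group was argued against, as the lowest null minus the highest heterozygous 3′ to 5′ log2 ratio was −1.77, the larger of the values for Gapdh and Actb, with overlapping groups in both, and without heterozygous 6 it was −0.35, again with overlap. The basal and luminal lists together had a median of 0.31 (0.03 to 0.43), where a lower share of urothelium needed one below −1. The basal list alone had the same median. Relative to the heterozygous mean, the 2 lists together lay at 0.17, 0.22 and 0.35 on null 1 to 3. On heterozygous 4 to 6 they lay at −0.15, 0.17 and 0.02. These genes were thus not lower as a set, but a lower share of urothelium stays open. The bound was set after the uroplakins had been seen, and gut-type epithelium may make some of these genes, which was not measured. Fewer or less mature umbrella cells, and a direct effect of the genotype on these genes, may explain the pattern. Upk2 and Upk3a, chosen after their values were seen, differed by 2.54 (SE 0.36). That SE treats the genes as independent, though both were measured on the same arrays. The difference does not exclude fewer umbrella cells, since which cells make each uroplakin was not measured.

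Heterozygous 6 had dim 5′ control signals. Degraded tissue RNA was argued against as the sole reason, since the 4 bacterial control RNAs, which do not come from tissue, had a mean log2 3′ minus 5′ difference of 4.69 on this array, above the highest other array by 1.75 (others 2.53 to 2.94, SD 0.158). A step after the control RNAs were added may therefore have differed on this array. The hybridisation controls lay between 14.1 and 14.4 on all 6 arrays. Without heterozygous 6, 42 genes were higher and 7 lower.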
